A study of Vitis vinifera with 60 samples.

How the data were processed

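Roots of 10 grapevine rootstocks were sampled with and without Rhizophagus irregularis. Per the labels' protocols, cuttings were rooted for 4 weeks, received about 200 spores per plant 2 weeks after transplanting and again a month later, and stood in 60 pots in a glasshouse at 24 °C by day and 18 °C by night. The deposited tables, 1 per library, list 55564 transcript models with the same order and lengths in all 60. Per the file headers, they give total gene reads, unique gene reads, an expression value, TPM, RPKM and the gene length. The authors' read counts are whole numbers without normalization. The deposited RPKM equals the count divided by length and library total to within a relative difference of 3.53e-04. TPM and RPKM were not used here. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. All model lengths are multiples of 3 (100% of models), so lengths are coding lengths. The tables hold no fungal genes, and colonisation of the roots was not measured in them.

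Total gene reads, the deposited counts, were summed over the models of each locus, which left 31845 loci. Of these, 23180 had 1 model and held 55.12% of the reads, and 1162 had no read in any library. In single-model loci, 96.0 to 98.4% of the reads of a library were placed uniquely. Reads shared between near-identical copies were counted by the authors in the total, so loci of multigene families are uncertain where their unique share is low. How reads common to several models of 1 locus were counted is not given. If they were not counted as unique, fits of uniquely placed reads also lose reads in loci with more than 1 model. How strand was treated is not given. No locus identifier matched the reference table (0 of 31845), so gene names are not given, and the lists of genes for phosphate transport, symbiosis signalling, lipid supply and defence, fixed before the data were examined, could not be run.

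Groups followed the sample titles. Loci were filtered with filterByExpr by group (minimum count 10, minimum total 15), which kept 25187, and libraries were scaled by TMM, with factors from 0.75 to 1.17. edgeR 4.0.16 in R 4.3.3 (with limma 3.58.1) fitted 20 group means to 60 libraries with trended dispersions (common dispersion 0.0461), robust quasi-likelihood and 40 residual degrees of freedom. The function for the dispersions was not fixed in advance: the numbers of calls under 3 of them were seen before 1 was kept, and the closing section gives the others. Contrasts were inoculated against uninoculated roots in each rootstock, their mean over 10 rootstocks, their differences among rootstocks (F test), each rootstock against the mean of the other 9 (adjusted over all 10 contrasts together), the mean of 7 hybrids against that of 3 species, and the differences among uninoculated groups (F test). Benjamini-Hochberg adjusted p below 0.05 was called. The SE of a log2 fold change is the fold change divided by the square root of its F value. It is approximate, and where a group held no read it depends on the prior count and does not measure the precision. Where a group held no read, ratios were computed with 3 counts over the group. Principal components and correlations used log2 CPM with a prior count of 2. So did a limma test of differences among rootstocks, in which the departures of the 60 libraries from a model of rootstock and inoculation were moved between libraries. The depth, 12440968 to 62521790 counted reads, limits low loci most in 420A.

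The loci named were fixed by a rule before the data were examined: in the mean contrast, the 10 largest rises and 10 largest falls among loci called, with a mean CPM of at least 1 and the same sign in at least 9 of 10 rootstocks, of which the first 2 of each are printed because the files do not pair identifiers with names. For each rootstock, the 2 largest rises and the largest fall were taken among called loci whose groups do not overlap. For the tests of differences, the 5 smallest p values were taken. These are described without identifiers.

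The tests were checked on simulated data drawn from the real loci's means and library sizes with loci changed by known folds (24608 loci tested). Unchanged loci had the same mean in every group, without the real differences between rootstocks. The spread followed the fitted trend, and changed loci had a mean CPM of at least 1. The recovery and the false calls thus hold for data that match the model, and may be worse in the real data. For inoculated against uninoculated 41B, 65.8% of loci changed by 1 on the log2 scale and 97.3% of those changed by 2 were recovered, with 7 calls among unchanged loci. For the mean contrast, 100% of both sizes were recovered, with 7 such calls, after the list of loci counted as changed was corrected to hold those with a nonzero mean from a change in part of the rootstocks. For the difference among rootstocks, 48.1% and 91.7% were recovered, for hybrids against species 88.5% and 100%, and for uninoculated rootstocks 58.3% and 96.2%. Alternatives were DESeq2 size factors, 2 other filters, DESeq2 1.42.0, fits of 6 libraries, a fold threshold, a replicate block, each library left out in turn and all SO4 libraries left out. Uniquely placed reads, thinning to equal depth, 2 other dispersion settings and leaving out 2 uninoculated libraries were added after seeing the data. Tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.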

Results

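Root transcript abundance was measured by RNA sequencing in 10 grapevine rootstocks, the root systems onto which wine and table grape varieties are grafted. Each rootstock was grown with and without Rhizophagus irregularis DAOM197198, a soil fungus that forms arbuscular mycorrhiza, a symbiosis in which the fungus grows inside root cortical cells and trades mineral nutrients for plant carbon. The 7 hybrid rootstocks were 41B, 110R, 140Ru, 420A, 1103P, 10114 and SO4, and the 3 wild species were Berlandieri, Riparia and Rupestris. With 3 libraries per rootstock and treatment there were 20 groups and 60 libraries. Counted reads per library ranged from 12440968 to 62521790. The 420A libraries were the shallowest, at 12440968 to 14580332 reads, and the 110R libraries the deepest, at 27107642 to 62521790 reads. The labels mention 60 pots but do not tie a library to a pot, so the p-values measure the spread between these samples, part of which may be technical. Groups followed the sample titles. For 3 SO4 libraries the title gives inoculation and the treatment field gives control, and 1 library titled as inoculated 10114 carries another rootstock's name in its source field. Loci are called by the identifiers of the deposited tables, which do not pair them with gene names, so 2 loci that rose and 2 that fell are named and the others are described as groups.

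Differences between the 10 rootstocks took 57.9% of the sum of squares of log2 CPM (counts scaled to library size) on 9 degrees of freedom, inoculation 18% on 1, the rootstock-specific part of the response 9.3% and the spread between replicates 14.7%. The first principal component held 22.1% of the variance, and along it inoculated minus uninoculated means ran from -78.7 in 10114 to -163 in 110R, with the same sign in each of the 10 rootstocks. All 60 libraries had their highest correlation with another library of their own group, the 3 SO4 libraries titled as inoculated and the 10114 library with the discordant source field included. No replicate pair agreed within sampling noise: over 60 pairs within groups, the chi-square per degree of freedom ranged from 5.18 to 112.81.

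**Figure D1:**
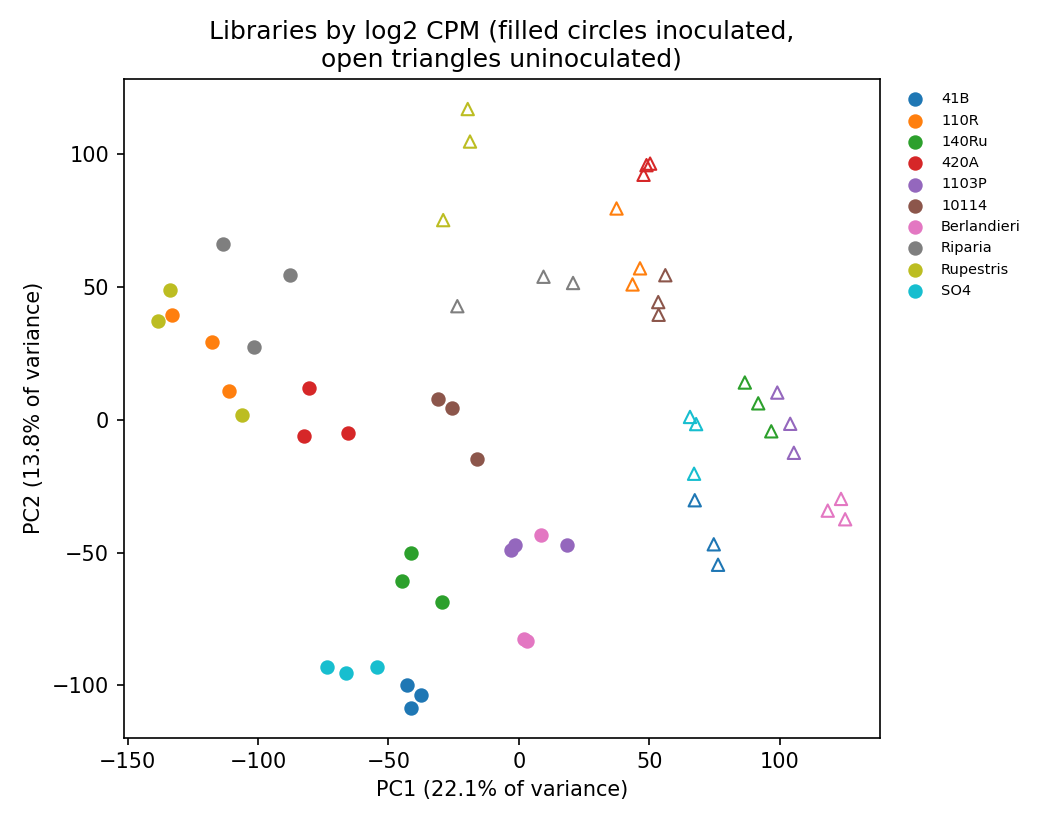
Principal components of log2 CPM for 60 libraries, PC1 (22.1% of variance) against PC2 (13.8%), in arbitrary units, with 1 colour per rootstock, filled circles for inoculated and open triangles for uninoculated roots. In each rootstock the inoculated libraries lie to the left of the uninoculated ones.

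The first comparison asked which loci respond to the fungus on average over the 10 rootstocks. Large changes were mostly rises. By the fitted log2 fold change, 1035 of the loci that rose and 166 of those that fell did so by at least 1, and 413 against 2 did so by at least 3. In all, 10671 of 25187 tested loci changed, 4745 upward and 5926 downward (edgeR quasi-likelihood test on 60 libraries, Benjamini-Hochberg adjusted p below 0.05). The largest rise was in VIT_200s0203g00015, with a coding length of 270 bases. It averaged 151 ± 66.9 CPM in inoculated roots (SD over 10 rootstocks) against 0.587 ± 1.26 CPM in uninoculated roots, and its fitted mean log2 fold change was 11.82 ± 0.29 (SE, adjusted p = 2.15e-27). In 5 rootstocks its 3 uninoculated libraries held no read, so the fitted value and its SE depend on the prior count there. Uninoculated Riparia held 3.7 ± 4.07 CPM and uninoculated Rupestris 2 ± 1.39 CPM (SD, n = 3). In Berlandieri, inoculated roots held 217 ± 41.5 CPM (SD, n = 3), at least 5410-fold higher than in uninoculated roots, with the latter set to a floor of 3 counts over the group, which covers counting error only. VIT_206s0080g00710, with a coding length of 558 bases, ranged from 75.3 CPM in inoculated 1103P to 1390 CPM in inoculated 110R, against 0 to 17 CPM in uninoculated roots (mean log2 fold change 11.43 ± 0.33 SE, adjusted p = 1.05e-28 by edgeR). The same limit holds for its fold change and SE, with 2 rootstocks lacking an uninoculated read. Both loci rose in each of the 10 rootstocks, and their smallest fitted log2 fold changes were in Riparia, at 4.77 and 4.86. All 10 loci with the largest mean rises were among those that rose in all 10 rootstocks, with mean log2 fold changes of 10.82 or more.

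Falls were smaller. VIT_208s0007g00330, with a coding length of 240 bases and 100% of its reads placed uniquely, fell in each of the 10 rootstocks. Its level was 62.2 ± 55.8 CPM in inoculated roots against 544 ± 377 CPM in uninoculated roots (SD over 10 rootstocks; mean log2 fold change -3.23 ± 0.14 SE, edgeR adjusted p = 2.34e-23). The fall ranged from -1.49 on the log2 scale in 140Ru to -5.27 in 110R. The locus with the largest mean fall, VIT_200s0480g00090, had a log2 fold change of -3.39 ± 0.41 (SE, edgeR adjusted p = 5.05e-09), passed the test in 7 rootstocks and reached 10.8 ± 4.27 CPM at most (SD, n = 3, uninoculated 420A). Of its 2002 reads, 154 (7.7%) were placed uniquely, so its value is uncertain. With those reads alone its log2 fold change was 0.68 (edgeR adjusted p = 1, against 2.36e-29 to 1 over all alternatives). So few reads over 60 libraries leave little power, so that fit does not decide whether the locus fell. The call of this locus also ended without Riparia_NM replicate 2 (log2 fold change -3.06, adjusted p = 1), which left both Riparia groups without a read. Over the loci tested, 1237 (4.9%), with a median level of 0.183 CPM, had at least 1 inoculated and at least 1 uninoculated group without a read, and the mean contrast has no power to call such loci.

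The response within each rootstock was tested next. The number of changed loci ranged from 1074 in 1103P to 9568 in SO4. In SO4, 5243 loci rose and 4325 fell, in Riparia 4186 rose and 4023 fell, and in 110R 4387 rose and 3561 fell. In 420A, 3404 loci rose and 2901 fell, in Rupestris 2904 rose and 2747 fell, and in 41B 2926 rose and 2584 fell. Rises outnumbered falls most in Berlandieri, 1103P and 140Ru. In Berlandieri 1247 loci rose and 278 fell, in 1103P 862 rose and 212 fell, and in 140Ru 1685 rose and 467 fell, which puts 81.8%, 80.3% and 78.3% of their calls upward. In 10114, 841 loci rose and 765 fell. The median log2 fold change of the loci that rose was 2.5 in 1103P, 2.28 in Berlandieri and 1.97 in 10114, against 0.76 in SO4 and 0.83 in 420A. With loci whose uninoculated group held no read set to their bound, these medians were 2.48, 2.28, 1.92, 0.76 and 0.83. The medians cover called loci only, so they depend on the length of each list and do not rank the size of the response. Over all tested loci, the median absolute deviation of fold changes was 0.232, 0.295, 0.328, 0.707 and 0.542 in the same order. Called rises of at least 3 on the log2 scale numbered 384, 497, 325, 562 and 584. The inoculated and uninoculated libraries did not overlap for 18.1% of tested loci in 1103P and 47.3% in SO4, where chance gives 10%. Among the 2 largest rises of each rootstock, 17 of 20 were of loci that rose in all 10 rootstocks.

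Numbers of rises held better than numbers of falls, and which direction had more calls was not settled in 4 rootstocks. With any 1 library of the rootstock left out, rises stayed within 1.5 times the reported number. Falls were 132 in Berlandieri without NM replicate 3, 135 without M replicate 3, 174 without M replicate 2 and 180 without NM replicate 1. In 1103P they were 105 without M replicate 3, 127 without M replicate 1 and 131 without NM replicate 2, and in 140Ru 255 without NM replicate 1 and 267 without M replicate 2. In 10114 they were 426 without NM replicate 2, 468 without M replicate 1, 474 without NM replicate 1 and 506 without M replicate 2, and in 420A 1785 without M replicate 3. Falls outnumbered rises in SO4 with DESeq2 (5126 against 4963), DESeq2 size factors (4836 against 4791), no filter (4671 against 4580) and a mean of at least 1 CPM (4950 against 4573). They also did in 110R with no filter (3810 against 3702), in Rupestris with no filter (3107 against 2455), with DESeq2 (3079 against 3059) and without NM replicate 1 (2781 against 2306), and in Riparia with no filter (3876 against 3872), without M replicate 2 (4308 against 4098), without NM replicate 1 (3496 against 3358) and with a replicate block (3982 against 3810). The counts in Riparia and Rupestris depended on the libraries in the fit. With the 6 libraries of the rootstock alone, 3989 loci changed in Riparia and 2668 in Rupestris, and the share that rose in Rupestris went from 51.4% to 68.3%. Without Riparia_M replicate 3 the count in Riparia was 5471, with 2619 falls, and without 10114_NM replicate 2 the count in 10114 was 1048.

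**Figure D2:**
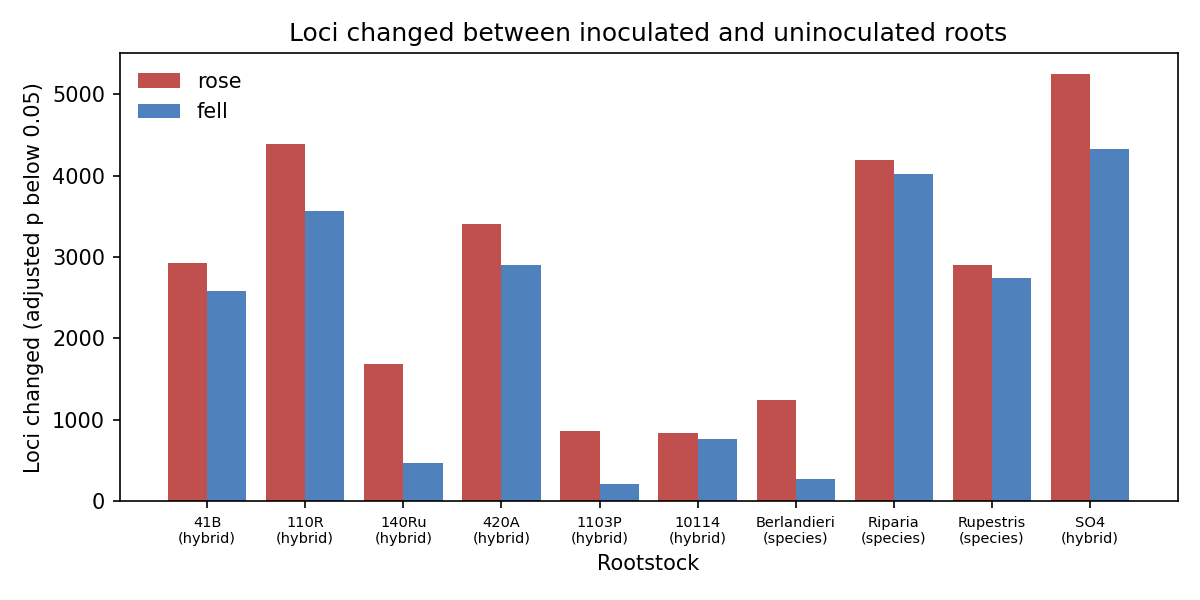
Number of loci that rose (red) and fell (blue) in inoculated against uninoculated roots of each rootstock, 3 libraries per group, at an adjusted p below 0.05 by edgeR's quasi-likelihood test. The bars for loci that rose run from 841 in 10114 to 5243 in SO4, and those for loci that fell from 212 in 1103P to 4325 in SO4.

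Shared responses were counted over the 10 lists, which have no control library in common. A total of 422 loci rose in all 10 rootstocks, where independent lists of the same sizes would share 1.04e-06. Another 164 rose in exactly 9. At least 5 rootstocks shared 1517 rises and 405 falls, against 48.2 and 12.3 for independent lists. The falls were 213 with uniquely placed reads and 189 without the 6 SO4 libraries, and the rises 1154 and 1216. In all 10 rootstocks, 3 loci fell. The 422 shared loci had a median fitted mean log2 fold change of 5.35. With loci without an uninoculated read set to the bound, their median log2 ratio per rootstock ran from 3.74 in 10114 to 6.07 in 110R.

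**Figure D3:**
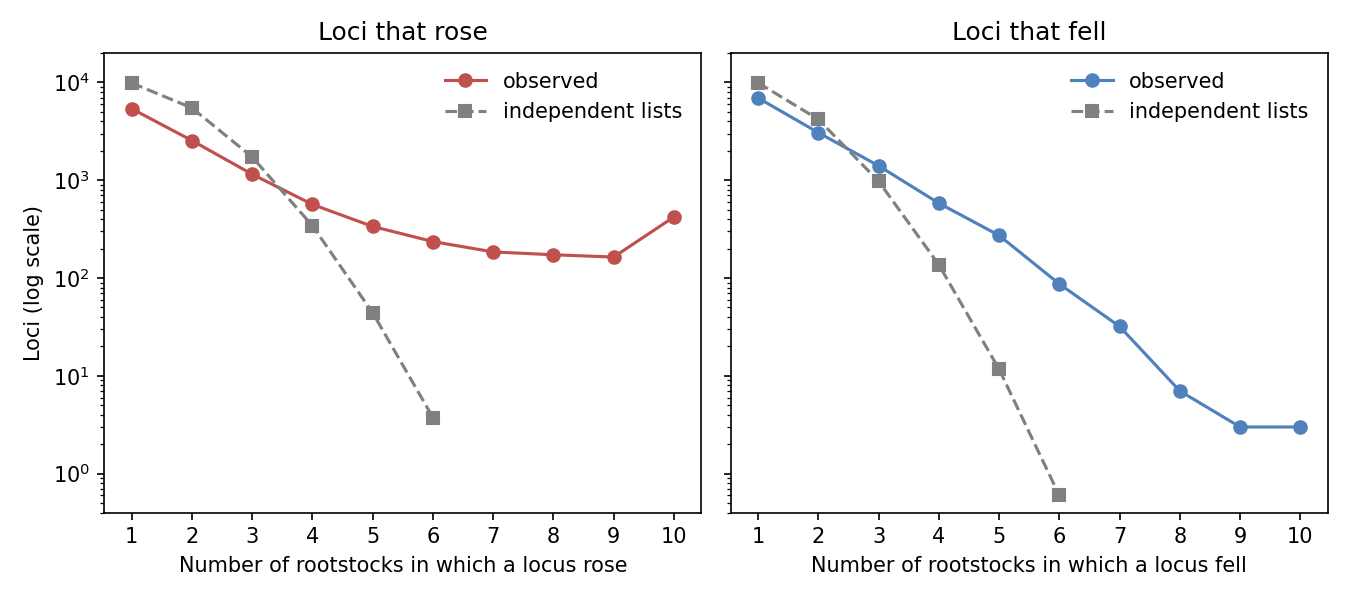
Number of loci (log scale) against the number of rootstocks in which they rose (left, red) or fell (right, blue), with the numbers that independent lists of the same sizes would give as grey squares, drawn where they are at least 0.5. Loci that rose in all 10 rootstocks number 422, more than those that rose in exactly 9 (164), while 3 loci fell in all 10. The grey squares treat every locus as equally likely to be called.

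The 422 loci took 1.85% to 10.6% of the counted reads in inoculated libraries and 0.363% to 0.968% in uninoculated ones. Their share in inoculated roots was 9.59% ± 0.87 in Rupestris, 9.16% ± 0.084 in 110R and 7.24% ± 1.2 in 420A (SD, n = 3). It was 6.61% ± 2.1 in SO4, 5.98% ± 0.57 in 140Ru, 5.72% ± 1.6 in Riparia and 4.4% ± 0.26 in 41B. The lowest shares were 2.96% ± 0.73 in Berlandieri, 2.79% ± 0.14 in 10114 and 2.52% ± 0.59 in 1103P. Because the set was chosen by the test of inoculation, the distance between inoculated and uninoculated roots is not independent evidence. The 3 SO4 libraries titled as inoculated held 4.54% or more against 0.476% or less in the uninoculated ones. Uninoculated Riparia, at 0.706% ± 0.23, and uninoculated Rupestris, at 0.666% ± 0.14, held the highest shares among uninoculated roots, and uninoculated Berlandieri the lowest, at 0.369% ± 0.0054 (SD, n = 3).

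**Figure D4:**
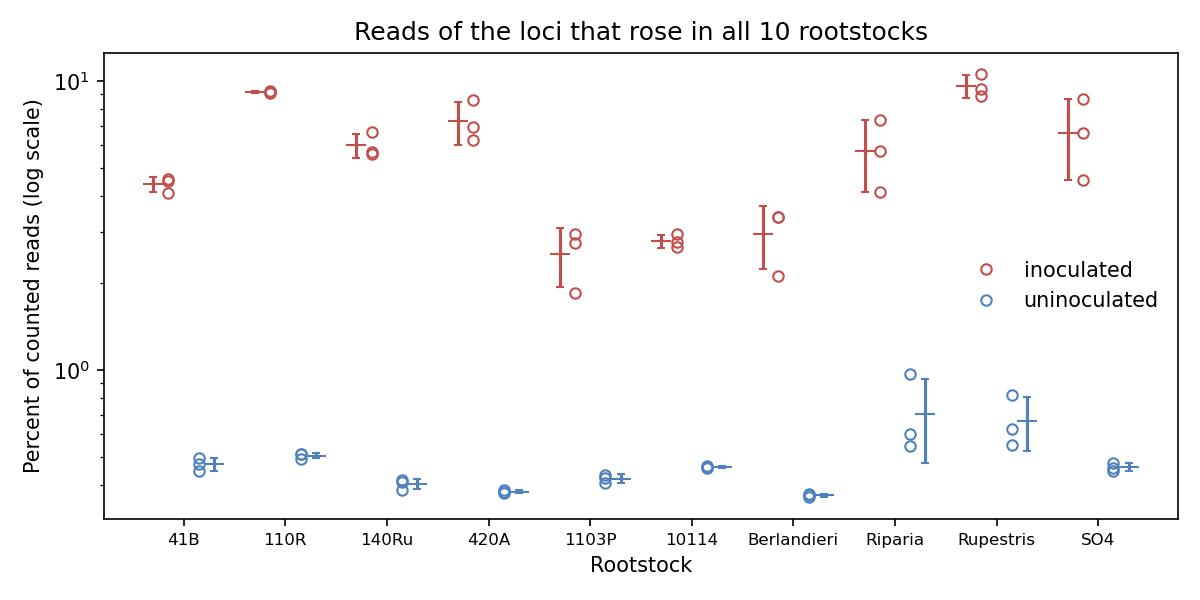
Percent of counted reads (log scale) from the 422 loci that rose in all 10 rootstocks, 1 circle per library, with bars for the mean and SD of 3 libraries drawn beside the circles, inoculated in red and uninoculated in blue. Inoculated libraries lie between 1.85% and 10.6%, and uninoculated ones between 0.363% and 0.968%, with Riparia and Rupestris the highest of the latter.

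Whether rootstocks respond differently was tested directly. The response differed among the 10 rootstocks for 14753 of 25187 loci (58.6%), and for 397 of the 422 shared loci (94.1%). Reads of the shared loci in uninoculated Riparia and Rupestris lower the fold changes there. Among the other 8 rootstocks, a test chosen after the results were seen, 12149 loci differed, and 299 of the 422 (70.9%). With only the uninoculated Riparia and Rupestris libraries richest in such reads left out, 14104 loci differed, and 376 of the 422 (89.1%). Without the SO4 libraries the count also fell, to 12548 loci. Leaving out other pairs of rootstocks was not tried, so how much of the drop among 8 rootstocks comes from these reads was not shown. In each of the 8, 15 to 72 of the 422 loci held no uninoculated read, which may also lower the power there. A total of 4729 loci rose in at least 1 rootstock and fell in at least 1 other, 1639 of them by at least 1 on the log2 scale in both directions. The 5 loci with the smallest p values had log2 fold changes from -0.72 in 420A to 3.71 in 110R for the first and from 0.15 in Riparia to 7.64 in 140Ru for the next, and 1 of the 5 belonged to the shared set. When each rootstock was set against the mean of the other 9, 15353 loci stood apart in at least 1 rootstock. The numbers were 5420 in Riparia, 5365 in SO4, 4900 in 110R and 4257 in 420A, and 950 in 1103P and 1017 in 140Ru. The coefficient of variation of the 6 libraries was 0.256 in Riparia and 0.274 in Rupestris, against 0.157 to 0.217 in the other 8. These tests use a dispersion shared by all rootstocks, so replicate spread may add to the number in Riparia, which was not tested. A total of 6341 loci were called in exactly 1 rootstock. For 3697 of these (58.3%) the response in that rootstock also differed from the mean of the other 9, and for the rest the difference did not pass its own test. Across genes, which are not independent replicates, fold changes correlated least with those of other rootstocks in Riparia, with a mean r of 0.39, and most in 140Ru, with a mean r of 0.588. With the 422 shared loci removed, these means were 0.169 and 0.261, and the lowest was 0.157 in 10114 and the highest 0.263 in SO4.

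The 7 hybrids were compared with the 3 species, which by general knowledge of rootstock breeding include both parents of 6 hybrids and 1 parent of 41B. The mean response of the 7 hybrids differed from that of the 3 species for 3423 loci, being higher in hybrids for 1924 and lower for 1499 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05). The median absolute difference was 0.57 on the log2 scale. Of the 422 shared loci, 91 differed, 79 with a higher fold change in hybrids and 12 with a lower one. Without Riparia_NM replicate 2 and Rupestris_NM replicate 1 these numbers were 56 and 20. With a single species in the contrast, a comparison chosen after the results were seen, they were 34 and 25 for Berlandieri, 119 and 37 for Rupestris and 263 and 7 for Riparia. Of the 422 loci, 72 held no uninoculated read in Berlandieri, against 1 in Riparia and 2 in Rupestris. Where uninoculated hybrids lack reads too, such a contrast may have no power. The smaller total for Berlandieri, 59, may partly reflect this. Reads of the shared loci in uninoculated Riparia and Rupestris lower the fold changes there, so the split does not measure a stronger rise in hybrids. Which direction had more loci depended on the settings: lower responses in hybrids outnumbered higher ones with DESeq2 (2184 against 2051), DESeq2 size factors (1737 against 1608), a mean of at least 1 CPM (1912 against 1612) and a difference of at least 1 on the log2 scale (452 against 241). Not all ways to part the 10 rootstocks into 7 and 3 were counted, but 100, the real one and others drawn at random. Of these, 43, the real one included, gave at least as many loci. The count thus does not set this grouping apart from others, and chance is not excluded. Without Riparia_NM replicate 2 and Rupestris_NM replicate 1, the uninoculated libraries of the 2 species with the most reads from the shared set, 2035 loci differed, and with uniquely placed reads 2203 did.

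Rootstocks were also compared without inoculation. Of 25187 loci, 23231 (92.2%) differed among the 10 uninoculated groups. The distance between the highest and the lowest rootstock was at least 1 on the log2 scale for 17484 loci (69.4%), at least 3 for 5389 and at least 5 for 1339. Among the loci with a distance of at least 1, 420A was the highest of the 10 for 2920 and the lowest for 2669, and Berlandieri was the highest for 2293 and the lowest for 2330. The 420A libraries were the shallowest, and the extremes were not recounted at equal depth, so counting noise may be part of its numbers. The rootstock found least often at either end was 110R, with 1177 and 1027 loci, followed by 10114, with 1118 and 1199. The locus with the smallest p ran from -2.4 log2 CPM in 140Ru to 7.55 in 41B. Reads of all rootstocks were counted on the same transcript models, so sequence differences between the species and those models may be part of these values, which was not tested.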

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

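The tests on reads of strongly induced loci in uninoculated roots, the test of the spread of fold changes, the use of 6-library fits against noise, the regroupings by limma and the tests of differences among 8 rootstocks and with uniquely placed reads were chosen after the results were seen. The thinning test, the bound for the spread between replicates and the other splits of the samples were set before their results were seen. No group held the 4 samples that a search for single outlying samples needs.

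The response to inoculation differed among the 10 rootstocks for 14753 loci, the response of at least 1 rootstock differed from the mean of the other 9 for 15353, and that of hybrids differed from that of species for 3423, each by a test of the difference itself. The difference among rootstocks was also significant for the 4 named loci, with edgeR adjusted p values of 2.06e-07 for VIT_200s0203g00015, 6.68e-08 for VIT_206s0080g00710, 0.0122 for VIT_200s0480g00090 and 7.85e-07 for VIT_208s0007g00330. Among the 8 rootstocks other than Riparia and Rupestris no difference was shown for the first 2 (0.73 and 0.522), while the last 2 differed (0.00703 and 3.16e-06). In these 8, each uninoculated group held 0 to 6 reads of the first and 0 to 14 of the second. That leaves little power to tell their fold changes apart. With only Riparia_NM replicate 2 and Rupestris_NM replicate 1 left out, the first 2 still differed among the 10 rootstocks (edgeR adjusted p = 2.65e-07 and 3.49e-09). The fold changes of the first 2 depend on the prior count in the 5 and 2 rootstocks without an uninoculated read. With uniquely placed reads, 7.7% of its total, VIT_200s0480g00090 did not differ (0.658), so its difference is uncertain. Shuffling inoculation labels within rootstocks, the test set in advance (4714 and 5772 loci in the highest of the other splits), also removes the response common to all rootstocks, so it does not bear on these differences. A test chosen after that keeps an equal response in every rootstock and moves each library's departure from it to another library. By limma, the real libraries gave 15218 loci for the difference among rootstocks and 16107 for 1 rootstock against the other 9. The highest other regrouping gave 4 and 3, and for both 1 of 100 regroupings, the real one, gave as many. A chance assignment of these libraries is excluded at this number. The moved departures still hold any rootstock-specific response, so the low counts are no rate of false calls. Effects of pots, to which libraries are not tied, are not excluded. With inoculation labels shuffled, the real labels stood apart for the mean contrast (10671 against 1 in the highest other) and for loci called in at least 5 rootstocks (1922 against 0). With rootstock labels shuffled, they did for uninoculated rootstocks (23231 against 7557). In each, 1 of 29 splits was as large, which excludes a chance assignment of libraries at this number. Shuffling puts the real differences into the spread within groups, so these counts too are no rate of false calls. For hybrids against species, 43 of the 100 counted splits of the rootstocks gave as many loci, so chance is not excluded. The highest others among those counted gave 7832, with 41B, Riparia and SO4 against the rest, 7177 and 6321. In each rootstock the 6 libraries allow 10 splits, too few for a share under 0.05. The real split, in its own fit, called 4944 loci in 41B, 6596 in 110R, 1715 in 140Ru, 6238 in 420A, 1009 in 1103P, 1344 in 10114, 1104 in Berlandieri, 3989 in Riparia, 2668 in Rupestris and 8249 in SO4. In each rootstock 1 split, the real one, called as many, and the highest other called 0.

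The number of changed loci differed 8.91-fold between 1103P and SO4, and 8.72-fold (1018 against 8877 loci) with all libraries thinned to 12440968 reads, which argues against depth. A rank correlation of 0 or higher between the coefficient of variation of the 6 libraries and the count was set in advance to count against the spread between replicates, and that bound was met (Spearman's rho 0.505, Pearson's r 0.392, permutation p = 0.14 and 0.27, adjusted p = 0.19 and 0.36 over 4 relations; r = 0.286 without Rupestris and Riparia), but a condition on p, not passed, was added after the value was seen, and the bound was wrong, since noise beyond a dispersion shared by all rootstocks can widen fold changes and add calls. The spread of fold changes over loci, which rose with the count (rho 0.988, r 0.987, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 4e-05; r = 0.992 without 1103P and Berlandieri), decides nothing for the same reason. In fits of 6 libraries with their own dispersion, SO4 still had 8.18 times the count of 1103P (8249 against 1009), which argues against such noise as the whole cause of the difference between these rootstocks. In Riparia and Rupestris, with the highest coefficients of variation (0.256 and 0.274), those fits, which also have fewer residual degrees of freedom, gave 0.49 and 0.47 of the count against 0.72 to 0.99 in the other 8, so noise stays open there, and a difference in the size of the response or in colonisation, which these tables do not measure, was not tested.

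Uninoculated Riparia and Rupestris held more reads of strongly induced loci than other uninoculated roots. Over 133 loci with a mean log2 fold change of at least 7, the sum was 242 to 2700 CPM in these 6 libraries. It was 9.06 to 149 CPM in the 24 other uninoculated libraries. The list of loci replaced an earlier one chosen on the other 8 rootstocks. All 6 lay above the highest of the 24, which argues against reads spilling over alike from all inoculated libraries. Spill-over confined to libraries of Riparia and Rupestris was not tested. Among the 24, uninoculated 10114 was highest, at 134 to 149 CPM. As a percent of the mean of its own inoculated libraries it held 1.06 to 1.18%, within the 0.559 to 8.67% of the 6. Its profile correlated less with that of its own inoculated roots (r = 0.48 to 0.528 across loci, against 0.886 to 0.981 in the 6). The highest of the 6, Riparia_NM replicate 2, reached 11.9% of the lowest inoculated Riparia library, which argues against swapped libraries. In 5 of the 6 the ratio to the inoculated mean varied over loci no more than in single inoculated libraries of these rootstocks (MAD up to 0.348), as material of inoculated plants of the same rootstock would give. Rupestris_NM replicate 2 varied more (0.623), and its profile correlated most with inoculated Riparia (r = 0.914 across loci, against 0.886 with its own rootstock). The bound of 0.348 came from inoculated Riparia. Rupestris_NM replicate 1 (0.313) lay above the highest inoculated Rupestris library (0.307). Only loci with at least 20 expected reads entered, 57 to 119 in the 6 libraries and 130 to 133 in the inoculated ones, so the spreads cover unlike sets of loci. Material of inoculated plants and a low level of colonisation of the uninoculated plants may both give this pattern. They cannot be told apart here, since the profile of roots with low colonisation was not measured. Neither was shown to account for Rupestris_NM replicate 2.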

How the results depend on the processing

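The comparisons, tests, filter, scaling, first set of alternative settings and rule for named loci were fixed before the data were examined, while uniquely placed reads, thinning, 2 dispersion settings and the fit without Riparia_NM replicate 2 and Rupestris_NM replicate 1 were chosen after seeing the data. Of 182 counts under alternatives, 166 stayed within 1.5 times the reported count and 16 moved further, and numbers of rises and falls moved more than these totals. The ratio to the reported count was 1.02 to 1.24 with DESeq2, 0.73 to 0.99 without the 6 SO4 libraries and 0.97 to 1.07 with the newer quasi-likelihood fit of edgeR, and all 16 counts stayed within 1.5 times with DESeq2 size factors and with estimateDisp's dispersions. A log2 fold change of at least 1 left 2207 loci in 41B, 3995 in 110R, 1194 in 140Ru, 2591 in 420A, 954 in 10114, 3428 in Riparia, 2487 in Rupestris and 3528 in SO4, with 1201 for the mean, 7309 for 1 rootstock against the other 9, 960 called in at least 5 rootstocks and 693 for hybrids against species, by its own construction. The count for hybrids against species was 2203 with uniquely placed reads and 2035 without the 2 doubted libraries. Of the 422 shared loci, 91 differed there, 76 without these libraries, and 59, 270 and 156 with Berlandieri, Riparia or Rupestris as the only species, all chosen after seeing the data. Loci without an uninoculated read, most frequent in Berlandieri, may lower its number. Fits of 6 libraries called 3989 loci in Riparia and 2668 in Rupestris. The cause was not tested for these. With 1 library left out in turn, 2 of 420 counts moved further than 1.5 times: 10114 ranged from 1048 (without 10114_NM replicate 2) to 1967, and Riparia from 5471 (without Riparia_M replicate 3) to 8406. Counted by direction, 15 of 240 numbers of falls and 0 of rises moved further than 1.5 times with 1 library left out, and the direction with more calls changed in 3. Under the other alternatives, of 148, 25 numbers of falls and 14 of rises moved and the larger direction changed in 14. Falls were 1709 in 41B, 303 in 140Ru, 138 in 1103P and 181 in Berlandieri with uniquely placed reads, 178 in Berlandieri with no filter and 255 in 140Ru in its own fit. For the named loci, 281 of 284 values kept direction and call. The exceptions were of VIT_200s0480g00090: 0.68 on the log2 scale with uniquely placed reads, which are 7.7% of its reads, -3.01 without the 2 doubted libraries and -3.06 without Riparia_NM replicate 2, each with an adjusted p of 1. Depth limits low loci, yet thinned libraries gave 0.88 to 0.98 of the counts. The gene lists and their set tests were not run, since no identifier matched a name.

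Replicate numbers were tried as a replicate block. Same-numbered libraries correlated above 0.1 in 8 of 30 pairs (median r 0.0095) and matched best with their own number in 8 of 30, so the numbers do not pair the samples. With the replicate block, 10526 loci changed on average over the 10 rootstocks, 13416 differed in response among them and 2992 between hybrids and species, and over the 15 counts it could give, the ratio to those reported was 0.82 to 0.99. Replicate number as a block over all libraries gave 23138 loci for uninoculated rootstocks.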

Other observations

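The tests on parent species, on hybrids of the same cross and on reads of the shared set were chosen after the results were seen, and the other 2 of the 5 hypotheses tried, on shared reads and coding length, before.

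Loci that rose in all 10 rootstocks often had neighbouring identifiers. Of the 422, 104 (24.6%) stood directly beside another member in identifier order among the tested loci, against a mean of 13.5 and a highest value of 38 in 10000 random sets of the same size. Reads shared between near-identical copies are a candidate explanation. With uniquely placed reads alone, 360 loci rose in all 10 rootstocks, 358 of them among the 422, and 28.9% of the 360 stood beside another, against 9.7% in the highest of 10000 random sets, which argues against it. Groups of adjacent, jointly induced genes remain a hypothesis, since the identifiers were not matched to positions and the copies may share sequence over part of their length.

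No difference in coding length was shown for the set. Its median was 1153.5 bases, against a median of 1156.5 bases (range 1012.5 to 1329) over 10000 random sets matched on mean CPM.

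Rootstocks with a larger share of reads in the 422 loci tended to change more loci outside them, a hypothesis that did not pass correction. Over 10 rootstocks Spearman's rho was 0.697 (permutation p = 0.03, adjusted p = 0.06 over 4 relations) and Pearson's r 0.685 (permutation p = 0.034, adjusted p = 0.068). The relation was first computed alone, where the raw p passes the threshold; the family of 4 relations and the adjusted criterion were set after that p was seen. Without Rupestris and 1103P, r was 0.709 (permutation p = 0.052) and rho 0.667 (permutation p = 0.083). No relation of median depth to the number of changed loci was shown (rho 0.37, r 0.295, permutation p = 0.3 and 0.43, adjusted p = 0.3 and 0.43; r = 0.536 without 420A and 110R).

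The hypothesis that uninoculated hybrids lie closer to both parent species than to the species outside their cross was not borne out. Of the 6 hybrids whose parents, by general knowledge of rootstock breeding, are both among the 3 species, 2 (10114 and SO4) had their lowest correlation with the species outside the cross, the number that chance gives on average (exact binomial p = 0.649, one-sided). Several of these hybrids share a cross and all were set against the same 3 species. They are not independent trials, so this p is approximate. The highest correlation across loci was mostly with a parent species, which was not tested against chance. It was with Rupestris in 110R (r = 0.956), Berlandieri in 140Ru (0.935) and 1103P (0.936), and Riparia in 10114 (0.94) and SO4 (0.942). Only 420A, from berlandieri and riparia parents, correlated most with the species outside its cross, Rupestris (r = 0.917, against 0.903 with Riparia and 0.899 with Berlandieri). Some margins were near ties, as for 140Ru (r = 0.916 with Riparia, outside its cross, and 0.915 with Rupestris). Parent similarity was also looked at through regression weights, loci silent in 1 species and correlations in several forms. Of these, only the count of lowest correlations is reported as a test. The sampled species plants need not be the parents of these hybrids.

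Whether hybrids of the same cross respond alike was not settled. Over the 4 such pairs the mean correlation of fold changes across loci was 0.623, against 0.571 in the other pairs of hybrids. In an exact permutation test over 5040 relabellings, p was 0.0619 (one-sided), so no difference was shown.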
